A study of Homo sapiens with 4 samples.

How the data were processed

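The series holds 4 one-colour arrays (SurePrint G3 Human GE v3, Cy3), 1 per condition, from HCT116 cells 48 hours after transfection of empty vector or the LMNA-V6 exU1-U3 plasmid, or of control or LMNA-V6 siRNA at 10 nM. Per the labels' protocols, 400 ng of total RNA was amplified and labelled; the labels name 2 different extraction reagents, RNAiso Plus in the sample fields and an RNeasy kit in the series text. Plasmids and siRNAs were delivered with different Lipofectamine reagents, per the labels, so in the main comparisons each treatment was set only against the control of its own reagent, and the 2 controls against each other as a yardstick. Some values below set the siRNA arrays against the mean of the 2 plasmid arrays, which crosses the reagents. Groups were taken from the labels.

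The authors deposited scanner files whose values are spot intensities. Per the file headers these were made with Agilent Feature Extraction 11.5.1.1, which subtracted background and removed a fitted surface trend within each array, and all 4 arrays lay on 1 slide with 1 scan time, so slide and scan cannot separate the groups. The headers' own median variation between copies of a spot was 7.68%, 25.3%, 19.8% and 12.2% for empty vector, overexpression, control siRNA and LMNA-V6 siRNA, outside the software's accepted range for 3 of the arrays. The deposited value table is on a log2 scale, with scaling, centring and filter unstated. Its differences between arrays correlated with those of the scanner signals after the shift described below (Pearson's r across 21655 rows from 0.9996 to 0.9999), and each row's median over the arrays was 0. Its column medians were -0.09, 0.02, 0.06 and 0.01 in the same order, the reason for its selection of rows stays unknown, and 8 of its rows were spike-in controls.

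The main values were log2 of the processed signal minus each array's 75th percentile of it over 60901 non-control spots. Spots flagged as outliers were left out, no spot was saturated, and copies of a probe were averaged. A probe was used in a comparison when well above background on both arrays; for a probe with several copies, at least 50% of its unflagged copies had to be. Of 58201 probes, 31104 were matched by RefSeq accession, without version, to a gene symbol in a RefSeq table of assembly GRCh38.p14; since the array's own annotation is of another build, no coordinates are given. The other 27097 probes were left out of gene results. A gene's value was its probe with the highest mean over the 4 arrays; probes that differed 2-fold in opposite directions are said to disagree.

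With 1 array per group no p-value was made across genes. Intervals over genes or array sectors, given further below, do not cover variation between arrays or cultures. Genes at least 2-fold apart (1 on the log2 scale) were counted. Technical error came from 278 probes spotted 10 times and above background: the SD of single-spot differences around their probe's mean, and the number of genes these deviations alone would put past 2-fold around the median of all genes. Copies flagged as outliers were kept in this error, unlike in gene values, so it may be too large. It covers hybridization and scanning, not cell culture, RNA or labelling. For pairs of comparisons, the correlation of these deviations over 2770 spot copies gave the value with no difference between genes; it was computed after the data were seen. That median was 0.12 for overexpression minus mock, -0.09 for LMNA-V6 siRNA minus control siRNA and 0.20 for control siRNA minus mock, a shift that the random lists share. Spike-in probes, 8 per array, had median differences of -0.09, 0.04 and -0.15 in the 3 comparisons. Each of 34 gene lists was described by its median difference and the percentile of that median among 10000 random lists of the same size drawn in 20 bins of mean signal; lists with fewer than 3 measured members were left out. For genes above background on only 1 of 2 arrays, the bound sets the bright signal against the higher of the dim probe's own signal and the lowest signal called well above background on that array. Where the dim probe's own signal was the higher, the value is the measured difference and not a lower limit.

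Lists, thresholds and the naming rule were fixed before the data were examined. Named for each comparison were the 12 largest differences in each direction, the 4 largest bounds in each direction, up to 4 members with the largest absolute difference of each list described, and LMNA; across comparisons, the 10 genes with the largest smaller difference in opposite and in the same direction. Genes with clone-style, LOC or accession names were not named. Some genes that the rule selects were left out of the text.

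Alternatives were quantile normalization, centring on the median of measured probes, loess of the difference on mean signal, normexp background correction with an offset of 50, no filter or a stricter filter on dim probes, the mean over a gene's probes, the deposited value table, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Normexp used the median spot signal, since the files used here hold no mean signal. A local surface correction, chosen after seeing the data, subtracted per array the median deviation of the 50 nearest unreplicated measured spots. It was run on simulated data with 200 changed genes per comparison. The simulated surface was the one estimated on these arrays, with independent noise added, so the drop in false calls was largely built in. For overexpression minus mock (13992 genes), 100% of genes changed 4-fold, 98.0% of those changed 3-fold and 40.0% of those changed 2-fold passed 2-fold with the correction, and 27 unchanged genes did, against 551 without it. For the siRNA comparison (13520 genes) 98.0% and 38.0% passed, with 13 unchanged genes against 124. For the 2 controls (13803 genes) 90.0% and 38.0% passed, with 19 unchanged genes against 141. Without the correction 46.0%, 48.0% and 40.0% of genes changed 2-fold passed in the 3 comparisons. Spot copies on the real arrays would still put 112 higher and 168 lower genes past 2-fold for overexpression minus mock after the correction. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.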

Results

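Messenger RNA was measured on 4 Agilent whole-genome expression arrays, each hybridised with RNA from HCT116 cells, an established human colon cancer cell line. The study asked how expression shifts when LMNA-V6, a transcript variant of the lamin A/C gene, is overexpressed or silenced. A plasmid carrying the exU1-U3 form of LMNA-V6 was set against empty vector (mock), and LMNA-V6 siRNA at 10 nM against control siRNA, each 48 hours after transfection. Every condition had 1 array, so no value below has a replicate check, no p-value is given across genes, and the errors are technical. The share of probe spots well above background was 48.2% on the empty-vector array, 45.2% on the overexpression array, 45.3% on the control siRNA array and 44.2% on the LMNA-V6 siRNA array. "Higher" and "lower" mean at least 2-fold apart unless a value is given.

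LMNA, the manipulated gene, had 3 probes, all well above background on the 4 arrays, and none differed 2-fold in any comparison. On the overexpression array the probes lay 0.17 and 0.21 above and, for the probe designed on NM_001282625, -0.17 relative to empty vector (log2 differences), against a spread between copies of a spot of 0.52 (SD of a log2 difference). On the LMNA-V6 siRNA array the 3 differences from control siRNA were -0.16, -0.13 and -0.14, against a spread of 0.39, and after the local correction described below -0.49, -0.12 and -0.35. For the first of these probes the direction turned with normexp, to 0.21, and its overexpression value of 0.17 turned with loess, to -0.07. Between the 2 controls they were 0.34, 0.64 and 0.55. The files do not say whether any of these probes lies in the V6-specific part, so they check neither the overexpression nor the silencing.

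The technical error differed between the arrays. Probes spotted 10 times had a median SD between their copies of 0.11 (log2) on the empty-vector array, 0.41 on the overexpression array, 0.30 on the control siRNA array and 0.18 on the LMNA-V6 siRNA array. Part of this spread followed position: in 48 sectors of the array, the median difference of overexpression minus mock ran from -0.71 to 0.61. Values after subtracting the local level around each spot, a correction chosen after seeing the data, are therefore given beside the main ones. It lowered the SD of a single-spot difference from 0.52 to 0.31 for overexpression minus mock, from 0.39 to 0.28 for the siRNA comparison and from 0.38 to 0.29 for the 2 controls. The median SD between copies rose on the empty-vector array from 0.11 to 0.15. It fell to 0.25 on the overexpression array, 0.25 on the control siRNA array and 0.17 on the LMNA-V6 siRNA array.

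**Figure D1:**
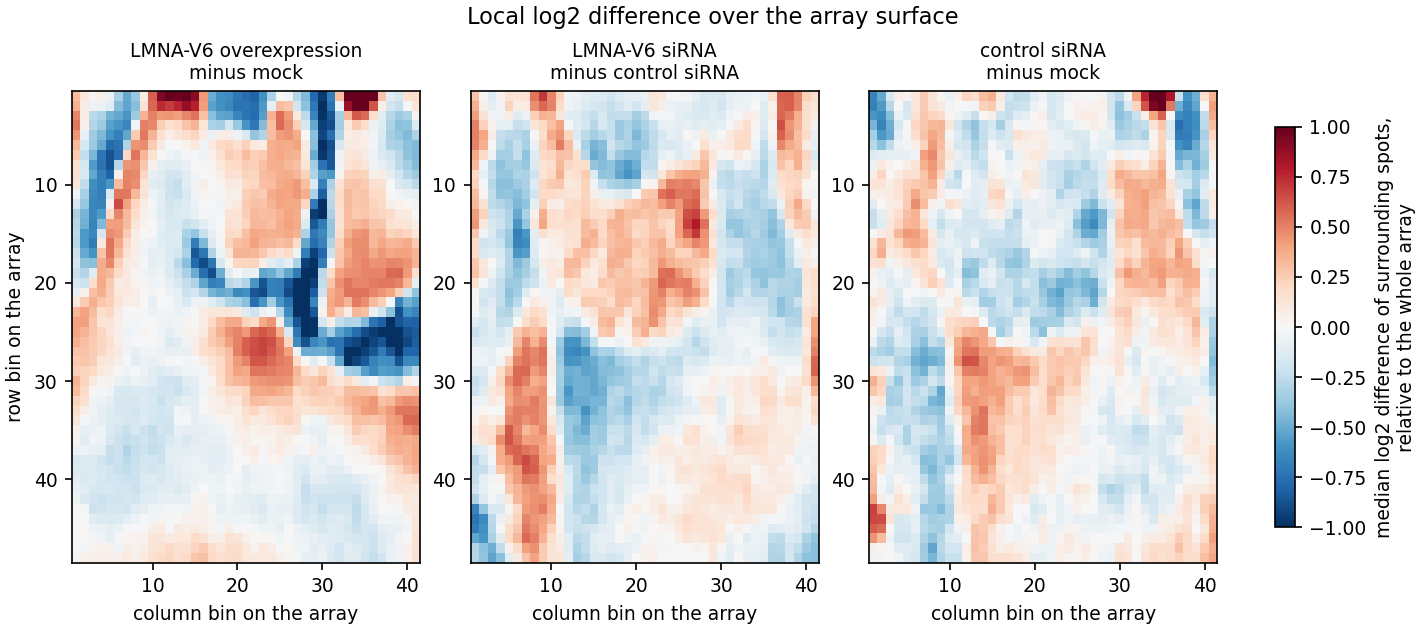
Local median log2 difference of the spots surrounding each position, relative to the whole array, over the array surface (48 row bins by 41 column bins) for the 3 comparisons; red is higher and blue lower on the first-named array. Bands and patches cover the overexpression comparison most strongly, where sector medians ran from -0.71 to 0.61, and the siRNA comparison less, from -0.35 to 0.28.

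On the overexpression array, genes of the ATF4 and amino acid response, the interferon response, the inflammatory and the immediate early lists lay low as groups, while cholesterol synthesis and heat shock genes lay high. The median of the 27 ATF4 and amino acid response genes was -0.60 (log2) relative to empty vector, against 0.15 for random lists matched on signal, and below all 10000 of them. Of these 27 genes 6 were lower and 0 higher, among them GARS1, the glycyl-tRNA synthetase (-2.04), the glycine transporter SLC6A9 (-1.60; -0.69 after the local correction), the transcription factor CEBPG (-1.44) and the amino acid transporter subunit SLC3A2 (-1.31; -0.84 after it). After the correction the list median was -0.43, with 3 members lower. The 25 type I interferon response genes had a median of -0.31 (random lists 0.11, percentile 0.0), with 1 member lower, the ubiquitin ligase HERC5 (-1.17; -0.61 after the correction), and with STAT2 at -0.93 and MX1 at -0.70. The 23 immediate early genes had a median of -0.25 (percentile 0.0), with only SPRY2, a feedback inhibitor of growth factor signalling, lower (-1.22), and with list medians of -0.15 after the correction and -0.02 with the stricter filter. The 18 NF-kB and inflammatory genes had a median of -0.37 (percentile 0.02): the chemokine CXCL8 was lower (-1.31), CXCL1 stood at -0.80 and the cytokine IL32 was higher (1.12; 0.58 after the local correction). The 19 long non-coding RNAs had a median of -0.16 (percentile 0.03), with CYTOR (-2.06) and KCNQ1OT1 (-1.36; -0.95 after the correction) lower and HOTAIR higher (1.28).

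The 24 cholesterol synthesis genes had a median of 0.37 on the overexpression array relative to empty vector (random lists 0.15, percentile 99.5). Their members went both ways, with 2 higher and 3 lower, among the latter the sterol desaturase SC5D (-1.85). The 14 heat shock genes had a median of 0.44 (percentile 99.3), with 3 higher and 3 lower. The HSP70 family members HSPA1B (1.23) and HSPA8 (1.12) were higher, and the HSP90 genes HSP90AA1 (-1.49) and HSP90AB1 (-1.17) were lower, the last 2 standing at -0.52 and -0.38 after the correction. TGF-beta and mesenchymal genes (15 measured, median -0.24, percentile 0.46) and YAP/TEAD targets (13 measured, median -0.20, percentile 0.90) also lay low. The TGF-beta call ended without a filter on dim probes, where the median was 0.04, with the stricter filter and with the mean over probes, and the YAP/TEAD call with normexp background correction. The unfolded protein response (median 0.38, percentile 98.95) and the apoptosis regulators (-0.07, percentile 0.97) fell inside the range of random lists after the local correction and with normexp, where the apoptosis median was 0.01 in each, and the apoptosis list also with the mean over probes. The 19 nuclear lamina and envelope genes lay inside it (median 0.17, percentile 71.3), with LMNB1 higher (2.30, and at the 2-fold limit after the correction) and LMNB2 lower (-2.43). Of 33 lists tested, 11 lay outside the central 95% of random lists, 7 of them in every setting tried. Several lay the same way in control siRNA minus mock, which subtracts the same empty-vector array: ATF4 (-1.53 there), interferon (-1.04), immediate early (-0.52), long non-coding RNAs (-0.83), heat shock (0.84) and the unfolded protein response (0.59). HSPA8 (3.32), HSPA1B (2.73) and LMNB1 (7.98-fold) were higher there as well, and CXCL1 (-4.62) and CXCL8 (at least 16.1-fold) lower. These values therefore do not separate overexpression from an empty-vector array that stands apart. The inflammatory list, measured without CXCL8 there, stood at -0.04 (percentile 11.9), and at -0.20 after the local correction (percentile 1.97). TGF-beta genes (0.76) and YAP/TEAD targets (0.95) lay the other way in control siRNA minus mock.

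At the level of single genes, 354 genes were higher and 795 lower on the overexpression array among 13992 measured on both arrays. The 12 largest higher differences were TSPYL2 (10.8-fold), the Notch target HES1 (8.58-fold), ZNF397 (8.57-fold), NGRN (8.46-fold), SLC33A1 (7.32-fold), the netrin receptor UNC5B (7.31-fold), LINS1 (7.10-fold), the translesion polymerase REV1 (7.03-fold), the non-muscle myosin MYH10 (6.49-fold), PPIB (5.88-fold), RBBP6 (5.86-fold) and AKAP8 (5.71-fold). UNC5B (2.65, log2) and PPIB (2.72) were also higher on the control siRNA array than on the same empty-vector array. The probes of ZNF397 disagreed, since its second probe lay at -1.59. The 12 largest lower differences were SGCB (9.92-fold), NAA15 (7.99-fold), MRI1 (7.92-fold), the anaphase-promoting complex subunit ANAPC16 (7.75-fold), NELFA (7.72-fold), ADO (7.31-fold), the cAMP-responsive factor CREB1 (7.30-fold), NACC1 (7.12-fold), RBM26 (7.06-fold), ST3GAL2 (6.94-fold), the adhesion molecule ALCAM (6.92-fold) and GDE1 (6.89-fold). CREB1 had 2 further probes, at 0.21 and 0.24. All 24 genes, each resting on a single spot, stayed at least 2-fold apart after the local correction, but with folds from 2.60 (PPIB) to 7.94 (SGCB), and TSPYL2 at 5.79-fold, NAA15 at 3.99-fold, NACC1 at 3.52-fold and MYH10 at 2.70-fold. Among genes above background on only 1 of the 2 arrays, PRAMEF12 (at least 8.08-fold), TNNT3 (at least 4.91-fold), ZNF853 (at least 4.53-fold) and the calcium-sensing receptor CASR (at least 4.51-fold) were seen on the overexpression array alone. ANO8 (10.8-fold as measured), CFAP263 (10.1-fold as measured), GATAD2B (9.32-fold as measured) and RIMS1 (at least 8.47-fold) were seen on the empty-vector array alone. CFAP263 stood at 4.49-fold and GATAD2B at 6.19-fold after the correction. Spot copies alone, with flagged copies kept, would give 346 higher and 591 lower genes, or 81.5% of the count. After the local correction 304 were higher and 349 lower, against 112 and 168 from spot copies, or 42.9%. The share of calls that were higher was 30.8%, and 46.6% after the local correction, 16.3% with loess, 12.5% with normexp and 69.4% without the filter on dim probes, where 2666 were higher and 1173 lower.

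On the LMNA-V6 siRNA array, relative to control siRNA, YAP/TEAD targets and growth factor genes were low and replication-dependent histone genes high. Against the mean of the empty-vector and overexpression arrays, these 3 lists stood at 1.05, 0.74 and -0.97 on the control siRNA array. On the LMNA-V6 siRNA array they stood at -0.06, 0.09 and -0.19, so the control siRNA array was the one farther away. The 13 YAP/TEAD targets had a median of -0.89 (random lists -0.10) and lay below all 10000 random lists, with 6 lower and 0 higher. They included the matricellular proteins CCN2 (-3.29, or 9.82-fold) and CCN1 (-2.95, or 7.74-fold), ARHGEF17 (-1.79) and AMOTL2 (-1.13). The 21 growth factor and receptor genes had a median of -0.59 (percentile 0.04), with 5 lower, among them PDGFA (-2.75), PDGFB (-1.97), HBEGF (-1.49) and the receptor FGFR3 (-1.10). A second PDGFA probe gave -2.29. This list fell inside the random range with normexp (percentile 15.5) and with the mean over probes. TGF-beta and mesenchymal genes (14 measured, median -0.50, percentile 0.70) had 3 lower, the plasminogen activator PLAU (-2.09), the SMAD repressor SKIL (-1.72) and THBS1 (-1.23). Immediate early genes (22 measured, median -0.44, percentile 0.34) likewise had 3 lower, FOSB (-1.20), FOS (-1.16) and ATF3 (-1.02; -0.59 after the local correction). The TGF-beta call ended with normexp and with the stricter filter, and the immediate early call with the stricter filter.

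The 13 measured replication-dependent histone genes had a median of 1.18 on the LMNA-V6 siRNA array relative to control siRNA and lay above all 10000 random lists, with 7 higher and 0 lower. The linker histone gene H1-3 (2.34), H2AC8 (2.04), H2BC12 (1.58) and H4C8 (1.51) led them, and after the local correction the median was 0.69 with 4 higher. In control siRNA minus mock the histone list stood at -1.16, so the control siRNA array was itself low for it. The ATF4 and amino acid response was high as a group (27 measured, median 0.32, percentile 99.9), with GARS1 (1.51) and the serine synthesis enzyme PSPH (1.51) higher and the arginine transporter SLC7A1 lower (-1.15). Its median was 0.16 after the local correction and 0.02 with normexp, where the call ended. Cytosolic ribosomal protein genes lay slightly high (32 measured, median 0.15, percentile 98.4), a call that ended with quantile, loess, normexp and the stricter filter, with a median of -0.06 under normexp. The unfolded protein response (20 measured, median -0.45, percentile 0.20) lay low, with PDIA6 (-1.22), DNAJB9 (-1.08) and HYOU1 (-1.01) lower, all under 2-fold after the correction. Hypoxia and glycolysis genes (28 measured, median -0.35, percentile 0.68), although HK2 (1.28; 0.73 after the correction) and P4HA1 (1.18) were higher and 0 members lower, and fatty acid synthesis genes (11 measured, median -0.48, percentile 1.43), with the desaturase FADS1 lower (-1.26), lay low too. The hypoxia call ended with normexp, and the fatty acid call with normexp, the stricter filter and the local correction. The 19 nuclear lamina and envelope genes lay inside the random range (median -0.28, percentile 8.84), but below it after the local correction (-0.38, or percentile 0.83), with LBR, which tethers chromatin to the inner nuclear membrane, lower (-1.56) and ICMT (1.32) and TMPO (1.21) higher. Of 32 lists tested, 11 lay outside the central 95% of random lists, 3 of them in every setting tried (histones, YAP/TEAD targets and the unfolded protein response).

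**Figure D2:**
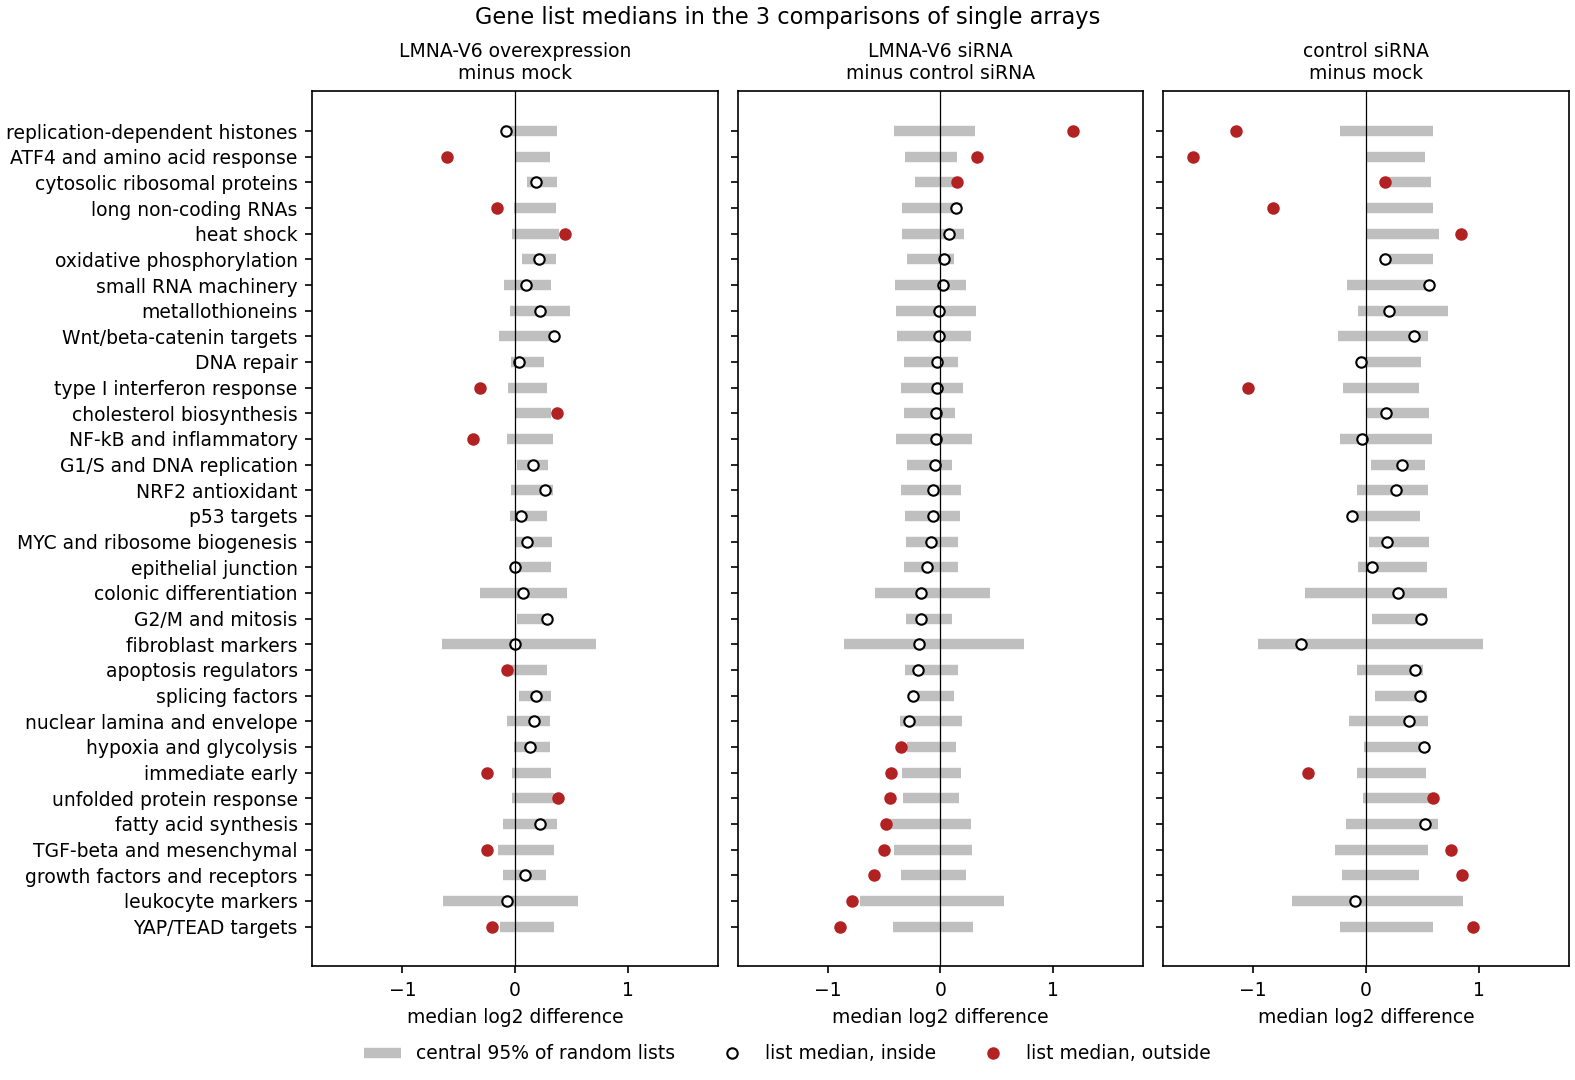
Median log2 difference of each gene list (points) in the 3 comparisons of single arrays, with the central 95% of 10000 random lists matched on signal (grey bars); red points lie outside the bars. YAP/TEAD targets lie at -0.89 and replication-dependent histones at 1.18 for LMNA-V6 siRNA minus control siRNA, and at 0.95 and -1.16 for control siRNA minus mock; lists with fewer than 3 measured members in a comparison are left out.

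Between the siRNA arrays, 700 genes were higher and 655 lower on the LMNA-V6 siRNA array among 13520 measured on both. The 12 largest lower differences were CCN2 (9.82-fold), the protocadherin PCDH1 (9.48-fold), CCN1 (7.74-fold), the cytokine IL11 (7.60-fold), PDGFA (6.71-fold), NCEH1 (6.63-fold), the cytosolic thiolase ACAT2 (6.61-fold), RRBP1 (6.49-fold), the anion exchanger SLC26A4 (6.22-fold), the mitotic kinase NEK6 (5.92-fold), CLDN6 (5.52-fold) and KCNE5 (5.46-fold). The 12 largest higher differences were the kinase HIPK1 (9.71-fold), the chromatin remodelling ATPase SMARCA4 (9.42-fold), ZBED2 (8.26-fold), CYB5B (7.53-fold), SNN (6.80-fold), CCM2 (6.52-fold), the small Cajal body RNA SCARNA17 (5.79-fold), XKR9 (5.54-fold), the RNA methylation factor WTAP (5.48-fold), RHBDF2 (5.39-fold), the actin-bundling protein FSCN1 (5.36-fold) and the fructose kinase KHK (5.34-fold). A second WTAP probe lay at -0.67, and all 24 genes stayed at least 2-fold apart after the local correction, with folds from 4.07 (SCARNA17) to 14.4 (PCDH1). BDH2 (at least 6.20-fold), the histone deacetylase HDAC4 (at least 6.19-fold), HDAC2-AS2 (at least 5.07-fold) and UNC5CL (measured difference of 2.32, log2) were above background on the LMNA-V6 siRNA array alone. PLEKHD1 (bound of 2.85, log2), FOXD2 (at least 5.90-fold), SLN (at least 5.72-fold) and FBN3 (5.10-fold as measured, or 3.25-fold after the correction) were above background on the control siRNA array alone. Spot copies alone would give 148 higher and 143 lower genes. After the local correction 489 were higher and 525 lower, against 44 and 44 from spot copies. The share of calls that were higher was 51.7%, and 63.1% with normexp and 38.8% without the filter on dim probes.

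Because the overexpression and siRNA comparisons share no array, their directions can be set side by side across the 13227 genes measured on all 4. Genes that were lower with overexpression and higher with siRNA numbered 82, against 40.8 for independent lists of the same sizes. Those higher and then lower numbered 23 (14.6), those higher in both 15 (15.7) and those lower in both 26 (37.8). The opposite-direction pairs with the largest differences were all lower with overexpression and higher with siRNA: H1-3 (-2.70 and 2.34), the RNA polymerase I factor TAF1D (-2.49 and 2.05), WTAP (-1.73 and 2.46), CCM2 (-1.71 and 2.71), BMS1P2 (-2.04 and 1.66), KLHDC9 (-1.96 and 1.65), the mitotic kinesin KIF18A (-2.29 and 1.65), FLVCR1-DT (-1.64 and 1.66), ANAPC7 (-2.39 and 1.64) and KATNBL1 (-1.75 and 1.62). In each of them the control siRNA array lay low with the overexpression array, and the LMNA-V6 siRNA array lay nearer empty vector. TAF1D, for example, stood at 3.58 on empty vector, 1.09 on overexpression, 1.02 on control siRNA and 3.07 on LMNA-V6 siRNA (log2 signal). The 2 low arrays had the largest SD between copies of a spot (0.41 and 0.30). The pattern therefore does not by itself show opposite responses to LMNA-V6. In the same direction, the stress gene GADD45B (-1.88 and -1.73), SKIL (-1.95 and -1.72), B4GAT1 (-2.05 and -1.66) and OFD1 (-2.13 and -1.48) were lower in both, and the Wnt regulator APC (1.96 and 1.71), TYW3 (1.61 and 2.33), SNORA2A (1.51 and 2.36), LRATD2 (1.74 and 1.42), GEMIN5 (1.44 and 1.39) and MAP4K4 (1.35 and 2.25) were higher in both. Over all these genes, which are not independent replicates, Pearson's r was -0.09 and Spearman's rho -0.08. Resampling array sectors put r between -0.161 and -0.029, and with normexp r was 0.002. Copies of the same probe, whose deviations from their mean carry no difference between genes, gave an r of -0.09 as well. After the local correction 46 genes went in opposite directions, against 22.4 for independent lists, and 19 in the same direction against 22.5. Of the 20 named, FLVCR1-DT, GADD45B, SNORA2A, GEMIN5 and MAP4K4 no longer passed 2-fold in both comparisons, and other probes of WTAP and OFD1 did not share their pattern.

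**Figure D3:**
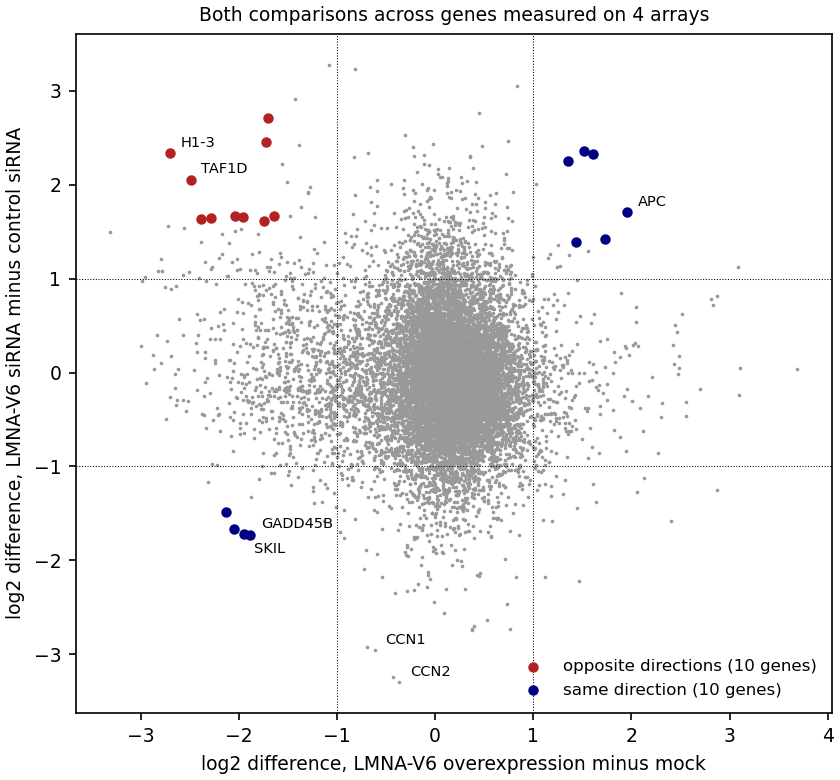
Log2 difference of each gene measured on all 4 arrays in the overexpression comparison (horizontal) and the siRNA comparison (vertical); dotted lines mark 2-fold, and coloured points are the 10 opposite-direction and the 10 same-direction genes. Genes lower with overexpression spread to the left with little trend on the vertical axis (r = -0.09 across genes).

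The 2 control arrays serve as a yardstick that includes the change from plasmid to siRNA transfection. On the control siRNA array, stress, interferon and histone genes were low and heat shock, YAP/TEAD and growth factor genes high relative to empty vector. Of 27 ATF4 and amino acid response genes 18 were lower and 0 higher (median -1.53, below all 10000 random lists), led by NUPR1 (-3.74), the stress-induced factor DDIT3 (-3.67), the mitochondrial PEP carboxykinase PCK2 (-2.94) and DDIT4 (-2.34). Of 23 interferon response genes 12 were lower (median -1.04, percentile 0.0), led by IFIT2 (-3.61), OASL (-2.49), IFI44 (-2.45) and the RNA sensor IFIH1 (-1.84). Of 13 histone genes 8 were lower (median -1.16, percentile 0.0), led by H1-3 (-2.28), H4C8 (-2.18), H2AC8 (-2.15) and H2BC12 (-1.61). Immediate early genes (22 measured, median -0.52) had 6 lower, among them EGR1 (-3.06), EGR2 (-2.70), JUN (-2.69) and ATF3 (-2.44), and 6 of 19 long non-coding RNAs were lower (median -0.83), led by CCAT1 (-3.06), and 2 higher, HOTAIR (1.14) and H19 (1.09). Of 13 YAP/TEAD targets 6 were higher (median 0.95, percentile 99.99), including CCN1 (1.86) and CCN2 (1.70), while the EGFR ligand AREG was lower (-2.15). Growth factor genes (21 measured, median 0.85, above all 10000 random lists), TGF-beta and mesenchymal genes (15 measured, median 0.76, percentile 99.9) and heat shock genes (14 measured, median 0.84, percentile 99.8) lay high, with HSPA8 at 3.32 and HSPA1B at 2.73. The TGF-beta call ended with normexp and with the stricter filter, and the growth factor call with normexp. The unfolded protein response lay high (20 measured, median 0.59, percentile 98.2), with DNAJB9 (1.89) and CRELD2 (1.17) higher, a call that ended without the filter and after the local correction. Cytosolic ribosomal protein genes lay low against matched lists (median 0.17, percentile 0.96), with medians of -0.15 under quantile normalization and -0.19 under loess, and the call ended with normexp and with unmatched lists.

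Between the 2 controls, 1284 genes were higher and 890 lower on the control siRNA array among 13803, more than in either LMNA-V6 comparison. The largest lower differences were the chemokine CXCL1 (24.6-fold), the stress cytokine GDF15 (14.2-fold), NUPR1 (13.3-fold), DDIT3 (12.8-fold), IFIT2 (12.2-fold), CXCL2 (9.20-fold), CCAT1 (8.36-fold), EGR1 (8.34-fold), IL21R (7.78-fold), PCK2 (7.67-fold), GOLT1A (7.67-fold) and ARRDC4 (7.63-fold). Second probes of CXCL1 (-3.22), CXCL2 (-3.17) and CCAT1 (-2.02) were also lower. The largest higher differences were IGDCC3 (14.6-fold), HSPA8 (9.99-fold), MSX1 (9.97-fold), the nuclear lamina gene LMNB1 (7.98-fold), COX20 (7.72-fold), POFUT4 (6.96-fold), SLC67A2 (6.62-fold), HSPA1B (6.61-fold), PPIB (6.58-fold), SAV1 (6.54-fold), HMGA2 (6.29-fold) and UNC5B (6.26-fold). After the local correction LMNB1 stood at 3.94-fold, COX20 at 3.53-fold, PPIB at 3.16-fold, POFUT4 at 2.67-fold and SAV1 at 2.62-fold, while the 12 lower genes ran from 5.45-fold (PCK2) to 19.7-fold (CXCL1). The second probe of COX20 lay at 0.04, that of POFUT4 at 1.07, and 2 further HMGA2 probes at 0.49 and -0.26. PLEKHD1 (at least 11.4-fold), TNNI1 (at least 8.81-fold), FGF18 (7.44-fold as measured) and ZNF853 (at least 7.23-fold) were above background on the control siRNA array alone, and the chemokines CXCL3 (at least 16.7-fold) and CXCL8 (at least 16.1-fold), INHBE (at least 10.7-fold) and RIMS1 (at least 9.23-fold) on the empty-vector array alone. Spot copies alone would give 276 higher and 30 lower genes. The share of calls that were higher was 59.1%, and 44.2% with quantile normalization, 37.8% with loess, 47.9% with normexp, 77.0% without the filter and 69.9% with the stricter filter. The median of all genes lay at 0.20 in the main setting and at 0.05 and 0.00 with the first 2 of these.

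**Figure D4:**
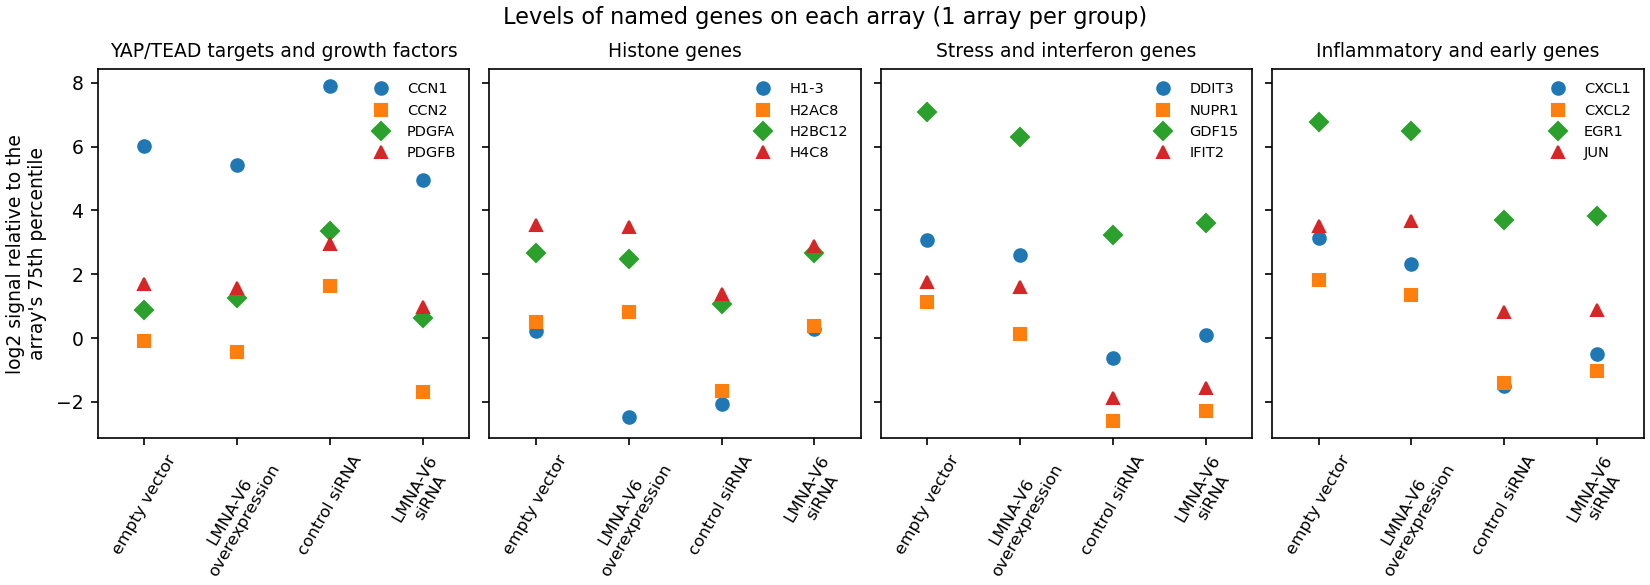
Log2 signal of 16 named genes on each array relative to that array's 75th percentile, 1 array per group, with no error bars because there are no replicates; only values of the same gene are comparable. CCN1 and CCN2 stand 1.86 and 1.70 above the empty-vector array on the control siRNA array, and -2.95 and -3.29 apart between the LMNA-V6 siRNA and control siRNA arrays; DDIT3 and IFIT2 are lower on the control siRNA array than on the empty-vector array.

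Some marker genes of other cell types were above background on the arrays, where 44.2% to 48.2% of all probe spots were. Of 10 fibroblast markers 3 were above background on each array, and of 9 leukocyte markers 4 on all arrays. Of 8 endothelial markers 1, VWF, was above background on all arrays, and of 10 squamous and mammary markers 2, KRT10 and SFN. Among 25 epithelial junction genes 23 were above background on all arrays, including CDH1 and EPCAM. Of 30 colonic differentiation genes only 8 were above background on each array and 6 on all arrays. These counts therefore do not by themselves identify the tissue of the cells. Leukocyte markers lay low on the LMNA-V6 siRNA array relative to control siRNA (5 measured, median -0.78, percentile 1.59), with 0 members 2-fold apart in either direction. After the local correction the median was -0.95 (percentile 0.26), with 2 members lower. The call ended with normexp, with the deposited table and without the filter on dim probes, where the median was 0.12.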

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

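Of the tests in this part, those on the overexpression counts and lists and on second probes were chosen only after the result was seen, and those on which siRNA array lies farther from the plasmid arrays before. Probes matched to no gene symbol were outside the comparisons: between the overexpression and empty-vector arrays 469 of 5812 such measured probes lay at least 2-fold apart, where spot copies alone would give 389, and between the siRNA arrays 465 of 5325, where they would give 114. After the local correction 255 were higher and 92 lower with overexpression, against 116 from spot copies. Between the siRNA arrays 202 were then higher and 183 lower, against 35.

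The 1149 single-gene differences between the overexpression and empty-vector arrays may largely be technical. Spots of the 795 lower genes lay where the surrounding spots were low as well, by -0.64 (log2) relative to all genes (95% bootstrap interval -0.66 to -0.61). Spot copies alone, with flagged copies kept, would give 81.5% of the count (42.9% after the local correction). Overexpression as the source of most of these single-gene differences is argued against by second probes: for 209 lower genes these lay only -0.10 from the median of all second probes (interval -0.14 to -0.001), against -0.70 for the same measure between the 2 controls. After the local correction 327 of the 795 lower and 119 of the 354 higher genes remained 2-fold apart. Uneven hybridization as the whole cause of the list medians is argued against, since 9 of 11 lists stayed outside the random range after the correction (ATF4 -0.60 to -0.43, interferon -0.31 to -0.36), but for the unfolded protein response (0.38 to 0.19, percentile 82.6) and apoptosis (-0.07 to 0.01) it stays open. An empty-vector array that stands apart stays open too, since 6 of the lists lay the same way in control siRNA minus mock (r across genes 0.30, spot copies 0.22). The inflammatory list was inside the random range there (percentile 11.9), but below it after the local correction (percentile 1.97). YAP/TEAD targets (-0.20 with overexpression, 0.95 there) and TGF-beta genes (-0.24 and 0.76) lay opposite ways.

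The siRNA comparison mirrors the comparison of the controls in part: YAP/TEAD targets, growth factors, TGF-beta genes, the unfolded protein response, histones and ATF4 genes, at -0.89, -0.59, -0.50, -0.45, 1.18 and 0.32 with LMNA-V6 siRNA, were at 0.95, 0.85, 0.76, 0.59, -1.16 and -1.53 in control siRNA minus mock, while immediate early (-0.44 and -0.52), interferon (-0.03 and -1.04), heat shock (0.07 and 0.84) and long non-coding RNA lists (0.14 and -0.83) did not, or barely, mirror; the shared control siRNA array alone gives an r of -0.76 between spot copies, against -0.63 across genes. Of 1327 genes at least 2-fold apart between the siRNA arrays and measured on all 4, the LMNA-V6 siRNA array was the farther from the mean of the plasmid arrays for 33.8% (95% Wilson interval 31.3% to 36.4%). The interval covers the sampling of genes, which are not independent, and not arrays or cultures. The comparison also crosses the 2 reagents. Genes were picked by this difference, and spot copies varied more on the control siRNA array (0.30 against 0.18), which by itself makes that array the farther more often. After the local correction the value was 32.2% of 983 genes, where spot copies alone would give 44 higher and 44 lower. Within these limits, both values argue against LMNA-V6 siRNA having moved most of these genes away from a level shared by the other 3 arrays. Spot noise on the control siRNA array as the whole cause is argued against by second probes, at -0.54 (interval -0.69 to -0.41) for 136 lower and 0.27 (0.17 to 0.38) for 177 higher genes relative to all second probes; among 62 genes with a second probe 2-fold apart the same way, the control siRNA array was the farther for 67.7% (interval 55.4% to 78.0%), which alone decided nothing. An effect of the control siRNA itself and an effect of LMNA-V6 siRNA that opposes a response to siRNA transfection stay open. A deviation of the control siRNA culture, RNA or labelling stays open too, since second probes on the same array share these. Replicates of the control siRNA sample and a second control siRNA would be needed to separate them.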

How the results depend on the processing

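Results were recomputed under each alternative, and the cause of each difference was not tested. Counts follow the threshold: at 1.5-fold they were 1719 higher and 1380 lower for overexpression, 1862 and 2275 for LMNA-V6 siRNA, 3655 and 2016 for the 2 controls, and 556 genes in opposite directions; at 3-fold they were 75 and 308, 148 and 110, 246 and 255, and 10. Without the filter on dim probes the higher genes numbered 2666 for overexpression, 1308 for LMNA-V6 siRNA (2064 lower) and 4760 for the controls (1423 lower), with 583 in opposite directions; the TGF-beta list was at 0.042 for overexpression and leukocyte markers at 0.121 for LMNA-V6 siRNA. The stricter filter gave 114 and 305, 283 and 235, 590 and 254, and 23. Loess gave 187 higher genes for overexpression and 742 for the controls. Ribosomal protein genes between the controls were at -0.145 with quantile normalization and -0.19 with loess. Normexp, run on median spot signals, gave 105 higher genes for overexpression, 273 lower for LMNA-V6 siRNA, 625 higher between the controls, 54 in opposite directions, a correlation of 0.002 (Spearman 0.031), LMNA at -0.068 between the controls and 4 lists outside the random range for LMNA-V6 siRNA. It also put apoptosis regulators at 0.012 for overexpression, ribosomal protein genes at -0.061 for LMNA-V6 siRNA, and CDC45 at -0.49 and MCM2 at -0.318 between the controls. The mean over probes put TRA2B at -0.031 between the controls. The local surface correction, chosen after seeing the data, gave 349 lower genes for overexpression, 46 in opposite directions, LMNA at 0.741 between the controls and apoptosis regulators at 0.014 for overexpression. The leukocyte marker call for LMNA-V6 siRNA ended with the deposited table, and the ribosomal protein call between the controls with unmatched lists.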

Other observations

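Small nucleolar and Cajal body RNAs, which guide RNA modification and formed no list fixed beforehand, lay high on the LMNA-V6 siRNA array. The median of 197 measured was 0.40 (log2) relative to control siRNA, above all 10000 matched random lists, with 31 higher and 2 lower; after the local correction it was 0.38, with 34 higher and 1 lower. SCARNA17 (2.53), SNORA2A (2.36), SCARNA16 (2.32) and SNORA38B (2.07) led them; SCARNA17 (-1.60) and SCARNA16 (-1.53) were lower on the control siRNA array than on the empty-vector array. On the overexpression array the class was at 0.17 relative to empty vector (percentile 97.1, or 99.9 after the correction). At 2-fold the members went the other way, with 4 higher and 15 lower of 204, or 2 and 5 after the correction. All measured genes did so too, with 354 higher and 795 lower of 13992, or 304 and 349 after the correction. More lower than higher members at 2-fold is thus not particular to this class. Against the mean of the plasmid arrays their median was 0.37 on the LMNA-V6 siRNA array and 0.10 on the control siRNA array, where all measured genes stood at 0.08 and 0.15. That comparison crosses the 2 transfection reagents. This set and these names were chosen after the values were seen.

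Type I interferon response genes lay low on both siRNA arrays relative to the mean of the plasmid arrays, at -1.29 on the LMNA-V6 siRNA and -0.95 on the control siRNA array, and in the other order, at -0.95 and -1.08, after the local correction. The ATF4 and amino acid response did the same, at -0.89 and -1.20. Immediate early genes were at -0.98 and -0.41. YAP/TEAD targets were at -0.06 on the LMNA-V6 siRNA array and 1.05 on the control siRNA array.

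The tests on histone genes were all chosen after the result was seen. Histone mRNAs were high on the LMNA-V6 siRNA array relative to control siRNA, but their median stood at -0.19 (95% bootstrap interval -0.44 to 0.17) against the plasmid arrays, where the control siRNA array stood at -0.97, which argues against LMNA-V6 siRNA raising them over all other arrays. A larger share of cells in S phase stays open: the G1/S and DNA replication list was at percentile 70.4 of random lists (median -0.05), with members going both ways. For uneven labelling of RNAs without a poly(A) tail, the small nucleolar RNAs were at percentile 52.5 in control siRNA minus mock, with 13 higher and 10 lower. Against the plasmid arrays they stood at 0.10 on the control siRNA array, where all measured genes stood at 0.15 and histones at -0.97. As a class the small nucleolar RNAs were thus not low with the histones on that array. A median inside the random range with members going both ways decided nothing about labelling. Between the siRNA arrays the small nucleolar RNAs lay high with the histones (median 0.40). There the LMNA-V6 siRNA array stood higher, at 0.37 where all measured genes stood at 0.08. Uneven labelling, including labelling that differed between the classes, stays open. A low histone level that belongs to the control siRNA array may account for the histone difference. Whether the cells or the hybridised sample carried that low level was not tested.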
